A study of Mus musculus with 4 samples.

How the data were processed

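The series holds bulk RNA-seq of mouse skeletal stem cells from sham-operated and ovariectomized wild-type mice, with 2 libraries per group. Per the labels' protocols, bone metaphyses were digested with collagenase, the cells were stained for the antigens CD51, CD200, CD105, CD90, 6C3, Tie2, Ter119 and CD45, and stem cells were sorted by flow cytometry. RNA was taken up in TRIzol and libraries were made with a SMARTER mRNA kit. All 4 samples carry the time 8 weeks, and the labels do not say whether this is the age of the mice or the time after surgery. Nothing in the labels says that the libraries of a group come from separate animals or from separate pools. The p-values of the single-gene tests therefore measure the spread between these samples, which may be technical.

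The authors deposited 1 table of read counts per gene for the 4 libraries, not normalized. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and counted with featureCounts 2.0.1, on the mouse build GRCm38 (mm10). The aligner, the annotation release, the strand setting and any filter are not given in the sources used here. The values are whole numbers that sum to between 18291436 and 23721078 per library. The table has 55487 Ensembl gene IDs. GENCODE M21 (GRCm38) gave a symbol, position, exon length and GC content for 55227 of them. The other 260 IDs were kept by ID, and held at most 0.0046% of the counts of a library. Genes were counted without a stated strand, so reads of overlapping genes on opposite strands cannot be told apart. Of the genes named in the text, Spp1, Cebpb, Ccn2, Gas1, Ccne2, Hspa1a, Mpo, Ramp2 and Xist share between 15.0% and 33.4% of their exon length with other annotated genes, and their values carry that uncertainty. Near-identical copies such as Hspa1a with Hspa1b, or the haemoglobin genes, can also split reads.

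From the counts, genes with enough reads were kept by filterByExpr at its default settings, which left 17120 genes. Library sizes were scaled by TMM, and the groups were compared with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (model with group alone), with Benjamini-Hochberg adjustment over the genes tested. A gene is called changed where the adjusted p is under 0.05. Fold changes are ovariectomy over sham. The SE of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM (counts relative to the scaled library total), given as mean ± SD over the 2 libraries of a group. The common biological coefficient of variation was 0.317, with 2 residual degrees of freedom and a prior of 5.29. A single count is worth between 0.0423 and 0.0519 CPM. Where a group has 0 counts, the fold is a lower bound against a floor of 3 counts per library. Where 1 group has few counts, the ratio is given with an exact binomial 95% interval. Bounds and intervals cover counting error only.

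Before the data were examined, 39 gene lists were fixed: sorting antigens, stromal, skeletal and other cell types, signalling pathways, stress, metabolic and cell cycle genes. The 38 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data and with fry. Camera asks whether the members of a list moved differently from the other genes. At the preset correlation it takes genes as nearly independent, so its p does not measure the spread between libraries. With an estimated correlation its p rests on the 2 residual degrees of freedom. A list that does not pass there is therefore not shown to be unmoved. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Genes named in the text were also chosen by a rule fixed before the data were examined. The rule took the 12 genes with the smallest p in each direction among called genes with an absolute log2 fold change of at least 1, a mean of at least 5 CPM, no overlap between the groups and an established symbol. It also took up to 4 called members of each list by smallest p (or, where none was called, 2 members with the smallest p), and 15 fixed genes: 7 sort antigens, 2 oestrogen receptors, Runx2, Sp7, Pparg, Tnfsf11, Tnfrsf11b and Xist. Any other gene in the text was chosen after its values were seen. A further 5 gene lists, used only in the closing section, were written after the data had been examined.

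The gene test and camera were tried on simulated data. In 5 simulations of the ovariectomy comparison over 17120 genes, with means, library sizes and spread taken from the real libraries and 200 genes changed in each, 26.8% of the genes changed by 1 log2 unit and 60.8% of those changed by 2 log2 units were called. Of 470 calls among these and the unchanged genes, 32 were unchanged genes. Calls among members of the shifted list described next are not in that number. Both groups were simulated with the same spread per gene. In the real data, log2 differences had an SD of 1.06 in the sham pair and 0.79 in the ovariectomy pair. The share of unchanged genes among real calls may therefore differ. A simulated list of 30 genes shifted by 0.7 log2 units was called in 5 of 5 simulations by camera, and an unshifted list in 0. Simulated genes were drawn independently of each other, whereas the estimated correlation within real lists reached 0.52 (chondrocyte) and 0.83 (endothelial). The simulation therefore does not show how often camera calls an unshifted list of correlated genes.

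Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, library totals), the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 5 CPM, robust dispersion, leaving out mitochondrial, ribosomal protein and haemoglobin genes, a replicate block, and leaving out each library in turn. An offset for GC content and exon length was added after the data had been seen. With 1 library of a group left out, the lone library is assumed to vary like those of the other group. The sources give no sequencing batch or date, so no batch could be tested.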

Results

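Bulk RNA-seq counts were compared between skeletal stem cells sorted from the long bones of sham-operated mice (2 libraries) and of ovariectomized mice (2 libraries), all given the time 8 weeks. Ovariectomy removes the main source of oestrogen and is a widely used mouse model of bone loss after menopause, and the series title places the comparison in the setting of osteoporosis. The libraries held 22935095 and 23721078 counts (sham 1 and 2) and 23228031 and 18291436 counts (ovariectomy 1 and 2), with counts in 25230, 25056, 26706 and 27459 genes. The 10 most abundant genes took 26.4% and 28.1% of the sham counts and 21.6% and 20.7% of the ovariectomy counts. Across genes, log2 CPM of the sham pair correlated with Pearson's r = 0.930 and of the ovariectomy pair with 0.959, against 0.908 to 0.928 between groups, and genes are not independent replicates. Counts differed by more than sampling noise in both pairs, with a chi-square per degree of freedom of 28.6 for the sham pair and 13.9 for the ovariectomy pair, so no library was a second copy of another. The first principal component (50.8% of the variance) separated the groups, with sham 1 and 2 at -81.1 and -37.2 and ovariectomy 1 and 2 at 55.1 and 63.2, and the second (31.2%) set the sham libraries apart from each other. Y-linked genes had 0, 2, 0 and 0 counts.

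The antigens of the sort were read first. The labels name the antigens stained but not the gate, and which were selected for or against is taken here from the usual sort of such cells. Itgav (CD51), an integrin subunit, was at 68.9 ± 2.23 CPM in sham and 70.5 ± 2.11 CPM in ovariectomy cells (log2 fold change 0.03 ± 0.13 SE, edgeR adjusted p = 0.942), and its sign turned under upper-quartile scaling and under the GC and length offset. Cd200 was lower after ovariectomy, at 164 ± 12.6 against 271 ± 48.1 CPM (log2 fold change -0.73 ± 0.15 SE, edgeR adjusted p = 0.0462), and lost its call with library totals as the only scaling (adjusted p = 0.0531). Of the antigens of lineages that such sorts leave out, Ptprc (CD45), the pan-leukocyte marker, was at 7.40 ± 3.03 CPM in sham and 5.0 ± 2.04 CPM in ovariectomy cells, and Thy1 (CD90) was too low to test, with between 3 and 5 counts per library. Tek (Tie2), an endothelial receptor, was at 0.223 and 5.52 CPM in sham 1 and 2 and at 7.53 and 9.76 CPM in ovariectomy 1 and 2. Enpep (6C3) had a log2 fold change of 1.23 ± 0.47 SE and Eng (CD105) one of 1.10 ± 0.35 SE (0.60 to 1.89 without 1 library). Neither passed (edgeR adjusted p = 0.220 and 0.150). Eng was, however, called higher with limma-voom (0.0471), at a mean of 5 CPM (0.0481), with no filter (1.34e-08) and with the replicate block (0.0121). Tek was called higher with no filter (edgeR adjusted p = 0.00617). Taken as lists, 1 of 2 antigens taken as selected for was lower over all genes and 1 adjusted over the list alone. Of the 4 tested antigens taken as selected against, 0 passed either way (camera adjusted p = 0.208), although without sham 2 that list was called higher (0.000728), and Tek and Eng with it (edgeR adjusted p = 3.42e-05 and 1.69e-05).

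Ovariectomy was followed by more increases than decreases. Of 17120 genes tested, 716 changed, 510 higher and 206 lower, and 372 of the higher and 70 of the lower genes changed by at least 2-fold. Higher genes made up 71.2% of the calls, 82.2% with library totals as the only scaling (718 higher, 156 lower, with the median gene shifted by 0.11 log2 units) and 58.5% with the GC and length offset (459 higher, 325 lower, shifted by -0.11). Both ovariectomy libraries lay on one side of both sham libraries for 8446 genes (49.3%), where chance gives 33.3%. At an unadjusted p under 0.05 there were 3154 genes, against 856 by chance. The calls rest on both ovariectomy libraries. Without ovariectomy 1 or without ovariectomy 2, edgeR called 0 genes (1788 and 1618 at an unadjusted p under 0.05), and every single-gene call below was lost, with its sign kept. In those fits the spread came from the sham pair alone, whose log2 differences had an SD of 1.06, against 0.79 in the ovariectomy pair. Without sham 1 or sham 2 there were 1290 and 1835 calls, and the DESeq2 test called 1355.

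Among the 12 leading genes that rose, Has1 (ENSMUSG00000003665, chromosome 17, 17843323 to 17855205, minus strand, GRCm38), a hyaluronan synthase, had the smallest p and went from 115 ± 29.8 to 3449 ± 315 CPM, a 30.1-fold increase (log2 fold change 4.91 ± 0.20 SE, edgeR adjusted p = 0.000362). Pla1a (chromosome 16, 38396117 to 38433145), a phospholipase, rose 29.9-fold, from 3.85 ± 1.03 to 115 ± 1.6 CPM. Ereg (chromosome 5, 91074622 to 91093646), a ligand of the EGF receptor, had 2 and 3 counts in the sham libraries and 381 and 301 in the ovariectomy libraries, a ratio of 143 (95% counting interval 60.8 to 441). Plau (chromosome 14, 20836660 to 20843385), the urokinase plasminogen activator, rose 46.4-fold from 0.490 ± 0.127 to 23.0 ± 1.55 CPM. Procr, the endothelial protein C receptor, which also marks stem cells of several tissues, rose 12.8-fold, and Sema3a, a secreted semaphorin, 11.7-fold. The chemokine gene Cxcl1 rose 9.80-fold, from 23.6 ± 4.82 to 232 ± 1.82 CPM. Gpnmb, a membrane glycoprotein, rose 8.57-fold, Lrrn4cl 6.01-fold, Sparcl1, a matricellular protein, 5.43-fold, Steap3, a metalloreductase, 5.29-fold and Ackr3, an atypical receptor of Cxcl12, 3.95-fold. The edgeR adjusted p of these 12 genes lay between 0.000362 and 0.000608.

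Decreases were smaller. The RNA with the smallest p among those that fell was Rn7sk (chromosome 9, 78175303 to 78175633), the 7SK small nuclear RNA that holds the elongation factor P-TEFb inactive, at 19.8 ± 2.23 CPM in sham and 1.61 ± 0.07 CPM in ovariectomy cells (12.3-fold lower, log2 fold change -3.62 ± 0.28 SE, edgeR adjusted p = 0.00189). Rn7sk is not an mRNA and the libraries were made with an mRNA kit. Its counts may therefore reflect how much of it the kit captured rather than its level in the cells. Mepe (chromosome 5, 104325329 to 104338611), a phosphoglycoprotein of mineralized matrix, fell 9.90-fold, from 19.9 ± 7.90 to 2.02 ± 0.52 CPM. Col10a1 (chromosome 10, 34389981 to 34397085), the collagen of hypertrophic cartilage, fell 4.16-fold from 1156 ± 156 to 278 ± 99.4 CPM. The secreted antagonists Chrdl1 (of BMPs) and Wif1 (of Wnt proteins) fell 2.22-fold and 2.25-fold, from 1010 ± 39.6 and 1148 ± 139 CPM in sham. Rbp4, a retinol carrier, fell 2.49-fold, Ppp1r10, a regulatory subunit of protein phosphatase 1, 2.30-fold, Hhipl2 2.17-fold, Susd5 2.11-fold, Scube1 2.06-fold, Nrep 2.04-fold and Sqle, an enzyme of cholesterol synthesis, 2.03-fold. The edgeR adjusted p of these 12 genes lay between 0.00189 and 0.00692.

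**Figure D1:**
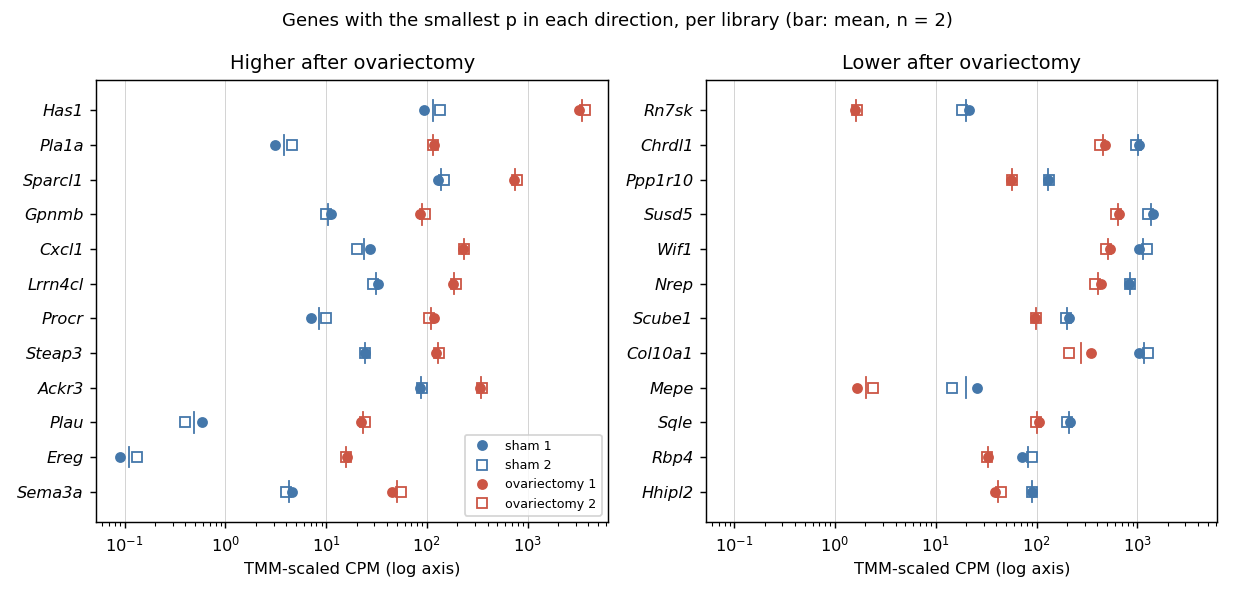
TMM-scaled CPM on a log axis for the 12 leading genes that rose (left) and the 12 that fell (right), with 1 point per library (circles, replicate 1; squares, replicate 2; blue, sham; red, ovariectomy) and bars at the group means (n = 2). The group means differ 30.1-fold for Has1 and 2.03-fold for Sqle, and genes were chosen so that both ovariectomy libraries lie on one side of both sham libraries.

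Most cartilage genes fell. Of 28 tested chondrocyte genes, 18 were lower and 2 higher (22 and 3 adjusted over the list alone), with a median log2 fold change of -0.78. Col2a1 (chromosome 15, 97975602 to 98004695), the main collagen of cartilage, went from 69282 ± 5497 to 38569 ± 2390 CPM (1.80-fold lower, log2 fold change -0.84 ± 0.08 SE, edgeR adjusted p = 0.00434). Col9a1 fell 1.81-fold, Col11a1 1.82-fold and Col11a2 1.70-fold. The members that rose were Prg4, the lubricin of joint surfaces (log2 fold change 1.14), and Matn4 (0.69), both named after their values were seen. The list was called lower by camera (adjusted p = 1.61e-21, between 5.44e-23 and 1.13e-12 over its other camera alternatives), but not with an estimated correlation (adjusted p = 0.353).

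A part of the bone-forming genes fell as well. Of 28 tested osteoblast genes, 12 were lower and 2 higher (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.61. Spp1 (osteopontin) fell 1.90-fold from 6057 ± 321 to 3185 ± 79.4 CPM, and Ibsp (bone sialoprotein) 1.98-fold from 11653 ± 839 to 5901 ± 831 CPM. Sp7 (osterix), a transcription factor required for osteoblast formation, fell 1.96-fold (edgeR adjusted p = 0.00893), and Runx2, which acts upstream of it, had a log2 fold change of -0.38 ± 0.15 SE that did not pass (edgeR adjusted p = 0.228). Col11a1 and Col11a2 are also members of the chondrocyte list, and 6 of the 28 genes stand in another list. Dlx3 (log2 fold change 1.26) and Dmp1 (0.62), named after their values were seen, rose. Camera called the list lower (adjusted p = 5.97e-13, between 3.59e-17 and 3.50e-07 over its other camera alternatives), and with an estimated correlation it did not pass (adjusted p = 0.346). With fry neither the chondrocyte nor the osteoblast list passed (adjusted p = 0.0969 and 0.127). Lists of fibroblast, pericyte and several blood cell markers, given below, were called higher by camera in the same libraries.

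A part of the stromal progenitor genes rose. Of 21 tested skeletal stem and progenitor genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.86. At a mean of 5 CPM the median was 0.32 over 15 members, with 7 higher. Summed CPM of the list did not rise, at 7434 and 6642 in sham and 6809 and 6410 in ovariectomy libraries. Ly6a (Sca-1), a marker of mouse mesenchymal progenitors, rose 4.94-fold from 24.7 ± 8.41 to 122 ± 5.53 CPM, Pdgfra 2.96-fold, Prrx1, a limb mesenchyme factor, 2.95-fold and Ctsk, a protease of osteoclasts and periosteal stem cells, 2.03-fold. Of the list, 7 genes stand in another list too, among them Pdgfra (fibroblasts), Ctsk (osteoclasts) and Acta2 (smooth muscle). Camera called this list higher (adjusted p = 4.69e-06, between 1.58e-06 and 0.00216 over its other camera alternatives, and 0.305 with an estimated correlation). Of the 18 genes of the LepR stromal niche, perivascular marrow cells that feed blood stem cells, 7 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 1.07. Igfbp4 rose 5.73-fold from 53.9 ± 10.1 to 309 ± 2.17 CPM, Ccn5 4.86-fold, Igfbp5 4.77-fold and Csf1, the macrophage colony-stimulating factor, 3.17-fold. The niche list was called higher by camera (adjusted p = 3.35e-19, between 9.85e-25 and 2.92e-08 over its other camera alternatives) and did not pass with an estimated correlation (adjusted p = 0.305).

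Inflammatory genes had the smallest camera p of the 38 lists. Of 22 tested genes of inflammation and NF-kB, 9 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.72. Besides Cxcl1, the cytokine Il6 rose 9.71-fold from 4.61 ± 0.86 to 44.8 ± 5.23 CPM, the chemokine Ccl7 10.3-fold and Ccl2 21.9-fold (log2 fold change 4.46 ± 0.39 SE, and 5.24 without sham 2). Camera called the list (adjusted p = 1.84e-27, between 1.54e-28 and 1.13e-12 over its other camera alternatives), fry did too (adjusted p = 0.0440), and with an estimated correlation it did not pass (unadjusted p = 0.0204, adjusted p = 0.305). Of 23 interferon-response genes, 5 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.14, and 8 were higher with the DESeq2 test, 10 with no filter and 12 without sham 2. Irf1, a transcription factor, rose 2.21-fold from 251 ± 11.9 to 553 ± 2.45 CPM, Gbp2 3.55-fold, Cxcl10 5.24-fold and Ifit1 5.31-fold. This list was called by camera (adjusted p = 7.22e-08, between 4.91e-08 and 6.01e-05 over its other camera alternatives, and 0.305 with an estimated correlation) and by fry (adjusted p = 0.0242). Lists of lymphocyte, monocyte and granulocyte markers, given below, were called higher by camera in the same libraries.

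Immediate-early genes, which respond to stimuli and to tissue dissociation within minutes, were higher in 11 of 27 cases and lower in 0 (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.43. With the GC and length offset 6 were called, and between 14 and 15 with library totals, the DESeq2 test, limma-voom, no filter or the replicate block. Klf2 rose 3.59-fold from 116 ± 19.9 to 416 ± 54.0 CPM, Atf3 1.87-fold, Zfp36 1.72-fold and Socs3, a feedback inhibitor of cytokine signalling, 1.70-fold. The camera adjusted p was 6.26e-11, between 6.26e-11 and 4.73e-07 over its other camera alternatives, and 0.305 with an estimated correlation. The sorted cells of both groups held much of this RNA, with 56250 and 52070 summed CPM in sham and 67740 and 67710 summed CPM in ovariectomy libraries.

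Lists of fibroblast and vessel wall markers had medians above 0, with a minority of their members called. Of 15 tendon and fibroblast genes, 6 were higher and 1 lower (8 and 2 adjusted over the list alone), with a median log2 fold change of 1.57. Dpt (dermatopontin) rose 6.56-fold from 16.4 ± 6.85 to 107 ± 1.18 CPM, Egfr 6.14-fold and Ly6c1 4.07-fold, while the summed CPM of the list, set by abundant members such as Fmod and Dcn, was 8988 and 11670 in sham and 9590 and 10130 in ovariectomy libraries. Camera called it higher (adjusted p = 7.20e-08, between 4.99e-14 and 0.00320 over its other camera alternatives, and 0.462 with an estimated correlation). Of 13 pericyte and smooth muscle genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 0.00104, between 6.36e-09 and 0.00603 over its other camera alternatives, and 0.483 with an estimated correlation). Des (desmin) rose 4.50-fold and Acta2 2.83-fold. Rgs5, a pericyte marker, was at 5.66 and 46.4 CPM in sham 1 and 2 and at 295 and 361 CPM in ovariectomy 1 and 2 (log2 fold change 3.65 ± 0.77 SE, 2.82 without sham 1 and 5.86 without sham 2, and not called with the DESeq2 test, adjusted p = 0.0504). Of 17 endothelial genes, 1 was higher and 0 lower, with the same counts adjusted over the list alone, and without sham 2 there were 9 higher genes. The member that rose was Ramp2 (4.51-fold), which shares 33.4% of its exon length with Vps25. The endothelial list had a median of 0.84 (0.21 without sham 1, 1.96 without sham 2 and 0.18 without ovariectomy 2) and summed CPM of 49.3 and 140 in sham and 183 and 222 in ovariectomy libraries. Camera called it (adjusted p = 0.00458) except without sham 1 (0.267) and without ovariectomy 2 (0.0715), and it did not pass with an estimated correlation (adjusted p = 0.743).

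Of 5 blood cell lists, 4 had medians above 0 and the megakaryocyte and platelet list one below 0. Of 15 tested erythroid genes, 5 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median log2 fold change of 2.48, also with Rhag at its bound. The 8 erythroid genes with a mean of at least 1 CPM in sham cells changed by 1.22 ± 0.10 SE in mean log2 level. Car1, an erythroid carbonic anhydrase, was at 0.134 and 0.712 CPM in sham and 51.3 and 87.1 CPM in ovariectomy libraries, Car2 rose 6.47-fold, and Rhag, with 0 counts in sham, was at least 35.8-fold higher. Klf1, a red cell transcription factor, had 4 counts in sham and 275 in ovariectomy cells, a ratio of 71.9 (95% counting interval 27.8 to 266), with all 4 sham counts in sham 1 and a log2 fold change between 5.19 and 10.18 without 1 library. The haemoglobin genes together were at 45.6 and 27.5 CPM in sham and 77.3 and 71.9 CPM in ovariectomy libraries. Camera called the erythroid list higher (adjusted p = 7.08e-13, between 6.87e-19 and 9.38e-08 over its other camera alternatives, and 0.305 with an estimated correlation). Of 14 granulocyte and mast cell genes, 3 were higher and 0 lower (6 and 0 adjusted over the list alone, and 6 higher without sham 1), with a median of 0.53, also with Ctsg at its bound (1.13 without sham 1 and 0.24 without ovariectomy 2, camera adjusted p = 0.000540, between 1.87e-08 and 0.0178 over its other camera alternatives, and 0.462 with an estimated correlation). Mpo (myeloperoxidase) was at 3.39 and 0.490 CPM in sham and 58.3 and 110 CPM in ovariectomy libraries. Elane had a log2 fold change of 3.13 (4.28 without sham 1 and 2.51 without sham 2), and Ctsg, with 0 counts in sham, was at least 17.0-fold higher. Klf1, Rhag and Ctsg lost their calls with limma-voom (adjusted p = 0.176, 0.177 and 0.176).

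Of 13 B and T lymphocyte genes, 3 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 1.94. Only 5 of the 13 had a mean of at least 1 CPM in sham cells. The 4 of these in no other list changed by 0.76 ± 0.18 SE in mean log2 level. Ebf1, which also stands in the LepR niche list, rose 4.41-fold from 17.5 ± 4.39 to 77.3 ± 14.99 CPM and Ighm 2.70-fold. The camera adjusted p was 4.30e-05, between 7.02e-06 and 0.00312 over its other camera alternatives, and 0.305 with an estimated correlation. Of 18 monocyte and macrophage genes, 1 was higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.95. It was Vcam1 (3.53-fold), which stands in the niche list too (camera adjusted p of the list = 0.000336, between 5.31e-05 and 0.00861 over its other camera alternatives, and 0.305 with an estimated correlation). Summed CPM of this list was 110 and 114 in sham and 185 and 240 in ovariectomy libraries. Of 10 megakaryocyte and platelet genes, 0 passed, also adjusted over the list alone, and the median was -0.69 (0.37 without sham 2 and 0.33 over 2 genes at a mean of 5 CPM, camera adjusted p = 0.172, and 0.00663 without sham 1). Ppbp had a log2 fold change of -3.12 ± 0.95 SE (-3.75 to -1.99 without 1 library, and called lower without sham 1, adjusted p = 0.00709), and Treml1 had 35 counts in sham and 1 in ovariectomy cells.

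**Figure D2:**
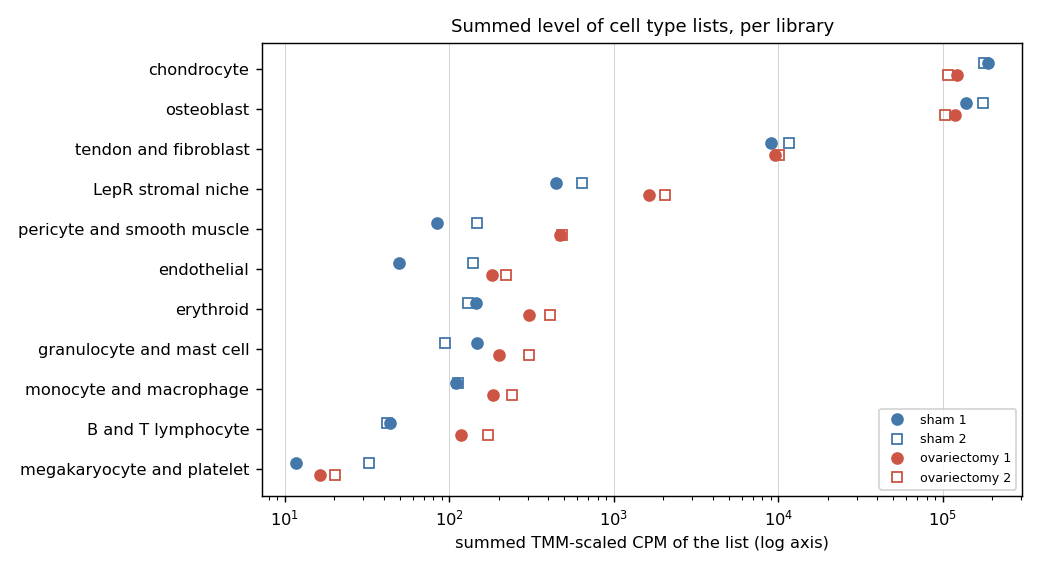
Summed TMM-scaled CPM (log axis) of 11 cell type lists in each library (circles, replicate 1; squares, replicate 2; blue, sham; red, ovariectomy). Chondrocyte genes fell from 187700 and 177800 CPM in sham to 121000 and 107200 CPM in ovariectomy libraries, whereas erythroid genes went from 144.6 and 129.3 to 303.8 and 407.8 CPM.

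Factors that act on osteoclasts, the bone-resorbing cells, moved both ways. Of 13 osteoclast regulators, 4 were higher and 1 lower (6 and 1 adjusted over the list alone), with a median log2 fold change of 0.80. Sema3a, Il6 and Csf1 are among those that rose (above). Tnfrsf11b (osteoprotegerin), the decoy receptor that blocks osteoclast formation, fell 1.74-fold from 1074 ± 27.7 to 618 ± 26.1 CPM (log2 fold change -0.80 ± 0.10 SE, edgeR adjusted p = 0.00775). Tnfsf11 (RANKL), which drives osteoclast formation, was at 8.36 ± 0.52 CPM in sham and 6.52 ± 1.80 CPM in ovariectomy cells and did not pass (edgeR adjusted p = 0.642). Camera called the list higher (adjusted p = 7.41e-08, between 7.98e-08 and 0.00287 over its other camera alternatives, and 0.305 with an estimated correlation), as did fry (adjusted p = 0.0179). The list holds factors that block and factors that drive osteoclast formation, so its direction does not tell the effect on osteoclasts. Of 9 osteoclast genes, 2 were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.48. Ctsk and Nfatc1 (1.63-fold, not called with the GC and length offset, adjusted p = 0.0684) rose and Mmp9 fell (log2 fold change -1.90, and -1.19 without sham 2). Camera called it (adjusted p = 0.0210) except without sham 1 (0.294), at a mean of 5 CPM (0.0515), with the replicate block (0.0981), with the GC and length offset (0.0681) and with an estimated correlation (adjusted p = 0.353).

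In the insulin-like growth factor axis, 3 of 16 genes were higher and 2 lower (4 and 3 adjusted over the list alone), with a median log2 fold change of 0.20. Those that rose were the binding proteins Igfbp4, Igfbp5 and Igfbp6 (2.77-fold), and those that fell include Stc2 (1.72-fold). Camera called the list higher (adjusted p = 0.00982) except without ovariectomy 1 (0.197), without ovariectomy 2 (0.332) and with an estimated correlation (adjusted p = 0.353). Of 18 adipocyte genes, 1 was higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.76, also with Cfd at its bound. The number of higher adipocyte genes was 4 with the DESeq2 test, 5 with the replicate block and 7 without sham 2 (median 1.35). Cebpb rose 2.27-fold. Pparg, the main adipocyte regulator, was at 0.735 ± 0.535 CPM in sham and 2.60 ± 0.08 CPM in ovariectomy cells. Its log2 fold change was 1.82 ± 0.74 SE (edgeR adjusted p = 0.250), and 2.86 without sham 2. The camera adjusted p of the adipocyte list was 0.00325, between 0.000259 and 0.0336 over its other camera alternatives, and 0.462 with an estimated correlation.

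Oestrogen receptors and responsive genes were not called as a list (camera adjusted p = 0.673). Of 11 tested genes, 1 was higher and 1 lower (2 and 2 adjusted over the list alone), with a median log2 fold change of 0.36. Esr1, the oestrogen receptor alpha gene, was at 12.1 ± 3.73 CPM in sham and 15.5 ± 0.66 CPM in ovariectomy cells (edgeR adjusted p = 0.579). Esr2 was too low to test, with 47 of its 49 counts in sham 2. Myc rose 1.59-fold, a call lost with the GC and length offset (adjusted p = 0.066), and Tnfrsf11b fell. Xist, the RNA of the inactive X chromosome, was at 149 ± 5.83 and 101 ± 0.88 CPM (log2 fold change -0.56 ± 0.12 SE, edgeR adjusted p = 0.0477), and its call was lost without sham 1 (0.0609) and with library totals (0.0886).

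The other signalling lists and the matrix list were not called by camera. Of 27 Wnt pathway genes, 3 were higher and 2 lower (4 and 6 adjusted over the list alone). Of the secreted Wnt antagonists, Sfrp4 (3.08-fold) and Sfrp2 (log2 fold change 2.19, named after its values were seen) rose and Wif1 and Frzb (2.23-fold) fell, and the receptor Fzd1 rose 3.80-fold. The median (0.03) and mean (0.15) of this list were above 0 and camera's direction was down (adjusted p = 0.774). Of 40 extracellular matrix genes, 7 were higher and 6 lower (12 and 13 adjusted over the list alone). Col4a1 and Col4a2, chains of basement membrane collagen, rose 6.44-fold and 4.57-fold and the cross-linking enzyme Loxl1 2.56-fold, whereas Thbs1 fell 1.71-fold. The median of the matrix list was -0.16, its mean 0.15 and camera's direction up (adjusted p = 0.887, and 0.00806 without sham 2). Of 12 Hedgehog genes, 2 were higher and 1 lower (2 and 2 adjusted over the list alone, median -0.11 and mean 0.01, camera adjusted p = 0.677, down). The co-receptors Cdon and Gas1 rose 3.02-fold and 2.55-fold and the receptor Ptch1 fell 1.94-fold. Of 31 BMP and TGF-beta genes, 3 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.395, and 0.0472 without sham 2), among them Ccn2 (1.495-fold, not called with the GC and length offset, adjusted p = 0.0503) and Ltbp1 (1.98-fold). Of 14 Notch genes, 1 was higher and 0 lower (2 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 0.229), and it was Rbpj (1.70-fold, not called with the GC and length offset, adjusted p = 0.059).

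Stress and cell fate lists were not called by camera. Of 22 senescence and p53 genes, 2 were higher and 0 lower (6 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.208, fry adjusted p = 0.0440), of which Phlda3 rose 3.001-fold. Of 20 apoptosis genes, 1 was higher and 0 lower with the same counts adjusted over the list alone (median 0.16, camera adjusted p = 0.422), and it was Fas (1.86-fold). Of 15 heat shock genes, 3 were higher and 1 lower with the same counts adjusted over the list alone (median 0.07, turning to -0.09 with the GC and length offset, camera adjusted p = 0.395). Hspb8 rose 3.14-fold, Hspb1 1.89-fold and Hspa8 1.43-fold, and Hspa1a fell 1.78-fold. Of 20 genes of the unfolded protein response, 1 was higher and 1 lower (2 and 3 adjusted over the list alone, median -0.10, turning to 0.01 with library totals, camera adjusted p = 0.208), with Asns 1.72-fold higher and Chac1 2.33-fold lower. Of 21 hypoxia genes, 0 were higher and 1 lower (1 and 1 adjusted over the list alone, median -0.07, turning to 0.04 with library totals, camera adjusted p = 0.774), and it was P4ha2 (1.45-fold), whose call was lost with library totals (adjusted p = 0.0862) and without sham 1 (0.0599). Chac1 lost its call with library totals (adjusted p = 0.052) and Hspa8 with the GC and length offset (adjusted p = 0.0658). Of 11 Schwann and neural genes, 2 were higher and 1 lower (4 and 1 adjusted over the list alone, median 0.73, camera adjusted p = 0.0748). Pmp22 rose 1.68-fold and Ncam1 fell 1.66-fold. The neural list was called without sham 2 (0.00499), without ovariectomy 1 (0.0189) and with the replicate block (0.0163).

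No member passed, over all genes or adjusted over the list alone, in the lists of cell cycle genes (38 tested), nuclear oxidative phosphorylation genes (62), mitochondrially encoded proteins (9), glycolysis (20), cytosolic ribosomal proteins (77) and skeletal muscle (8). The median log2 fold changes were 0.13, 0.17, -0.20, -0.05, -0.02 and -0.16, and the camera adjusted p values were 0.439, 0.160, 0.229, 0.673, 0.429 and 0.641. The medians of glycolysis (0.05) and of ribosomal proteins (0.08) were above 0 with library totals as the only scaling. The skeletal muscle list had a mean of 0.13, opposite in sign to its median and to camera's direction. The members with the smallest p were Ccne2 (log2 fold change -1.10 ± 0.29 SE) and Mcm5 (1.09 ± 0.31 SE) for the cell cycle, Ndufb7 (0.65 ± 0.20 SE) and Cox6b1 (0.41 ± 0.16 SE), mt-Co1 (-0.31 ± 0.13 SE) and mt-Cytb (-0.20 ± 0.11 SE), Pfkl (-0.46 ± 0.12 SE) and Eno2 (1.37 ± 0.39 SE), Rpl3 (-0.29 ± 0.13 SE) and Rpl22 (-0.42 ± 0.19 SE), and Acta1 (2.07 ± 0.59 SE) and Tnni2 (-0.75 ± 0.23 SE). Of these, Ccne2 and Mcm5 were called with the DESeq2 test (adjusted p = 0.0325 and 0.0232), at a mean of 5 CPM (0.0396 and 0.0476), with no filter and without sham 1. Pfkl was called with the DESeq2 test (0.016), limma-voom (0.0467), at a mean of 5 CPM (0.0345) and without sham 2 (0.0482), and Eno2 with no filter (0.00722), with the replicate block (0.0393) and without sham 2 (0.018). Acta1 was called without sham 2 (0.0303) and Tnni2 without sham 1 (0.0337). Single libraries changed some of these list results. Cell cycle genes were called higher without sham 1 (0.0210), oxidative phosphorylation genes higher without ovariectomy 2 (5.77e-07) and mitochondrially encoded genes lower without ovariectomy 1 (0.0253). Ribosomal proteins were called lower without ovariectomy 1 (0.000215) and higher without ovariectomy 2 (0.00994). Over the 38 lists, camera called 16 higher and 2 lower, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05, smallest adjusted p = 0.305), and fry called 4. Those 4 were the inflammation, interferon, osteoclast regulator and senescence lists. The fry adjusted p was 0.0672 for stem and progenitor genes and for immediate-early genes. It was 0.0969 for the LepR niche list and 0.0812 for the erythroid list.

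The numbers of called list members depend on the fit. Over the alternatives that keep both ovariectomy libraries, the number of higher members moved by more than 1.5 times in 30 of 39 lists and the number of lower members in 15, and the median turned its sign in 9 lists over all alternatives. With both ovariectomy libraries kept for the counts and all alternatives for the medians, the higher members numbered 7 to 13 in the LepR niche list (median 0.72 to 1.64), 4 to 10 in the erythroid list (median 1.06 to 3.05), 2 to 6 in the B and T lymphocyte list (median 1.28 to 2.36), 1 to 5 in the monocyte list (median 0.65 to 1.16) and 3 to 5 in the pericyte list (median 0.77 to 1.62). They numbered 3 to 6 in the insulin-like growth factor axis (median 0.05 to 0.56), 1 to 5 in the osteoclast list, 2 to 5 in the Schwann and neural list (median 0.15 to 0.90), 1 to 7 in the BMP and TGF-beta list (median -0.06 to 0.23), 0 to 4 in the Notch list, 1 to 5 in the senescence list, 0 to 2 in the oestrogen list and 0 to 4 in the cell cycle list. In the Wnt list 3 to 5 were higher and 2 to 5 lower (median -0.18 to 0.13), and in the matrix list 7 to 12 and 5 to 10. The median of skeletal stem and progenitor genes lay between 0.32 and 0.98 and that of skeletal muscle genes between -0.76 and 0.97. Cartilage genes kept 18 to 21 lower members and osteoblast genes 11 to 16.

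**Figure D3:**
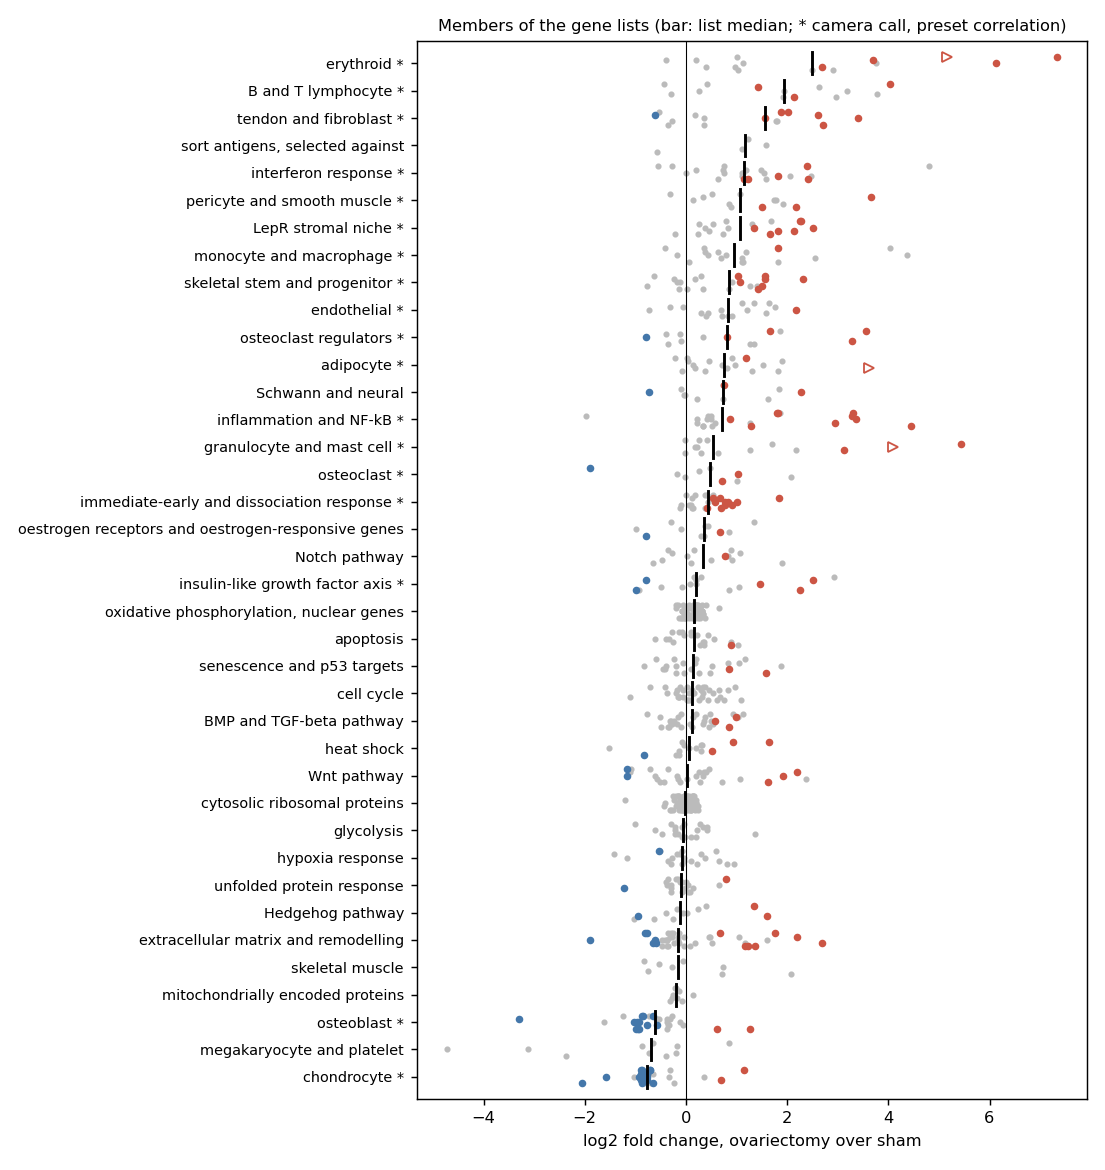
Log2 fold change (ovariectomy over sham) of the tested members of 38 gene lists, with called genes in red (higher) or blue (lower), other genes in grey and a bar at each list median. Open triangles mark lower bounds of genes with 0 counts in sham, and asterisks the 18 lists called by camera, from the chondrocyte list (median -0.78) to the erythroid list (median 2.48).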

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

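The GC and length offset and its results were chosen only after the data had been seen, and all other alternatives beforehand. All 716 called genes kept their sign in every alternative that tested them, which was 641 of them at a mean of 5 CPM. Counts of changed genes, higher and lower, stayed within 1.5 times of 716, 510 and 206 with DESeq2 size factors, upper-quartile scaling, library totals, robust dispersion and without mitochondrial, ribosomal and haemoglobin genes. The DESeq2 test called 1355 (893 and 462). With no filter there were 1656 (1112 and 544) and at a mean of 5 CPM 1105 (699 and 406). Limma-voom called 313 lower genes and the GC and length offset 325. The cause of these differences was not tested. Leaving out 1 library at a time gave between 0 and 1835 changed, 0 and 1277 higher and 0 and 558 lower genes. Both values of 0 came from leaving out an ovariectomy library, which leaves the sham pair to set the spread. Of 103 called named genes, all 103 lost the call in each of those 2 fits, and at most 6 in any other alternative (GC and length offset).

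The replicate numbers pair no animals, litters or days in the labels, so the samples share only a number. Deviations of same-numbered libraries from their group means correlated at 0.0043 (Pearson) and 0.0063 (Spearman) across genes. With the replicate block, 1074 genes changed, 745 higher and 329 lower, and 18 lists were called, 17 of them also called without it.

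Of 18 called lists, 18 were also called with DESeq2 size factors, 16 at a mean of 5 CPM (36 lists tested), 17 with the GC and length offset, between 16 and 18 without 1 library (18 to 22 lists called in all), 3 by fry (of 4 in all) and 0 with an estimated correlation (cause not tested, although the preset correlation of 0.01 is below the estimate for most lists that lost the call). Lists with an estimate below 0.01 lost the call too, namely skeletal stem and progenitor (-0.0044), interferon (-0.0325), osteoclast regulators (-0.0617), osteoclast (-0.11) and monocyte (0). For those lists the values argue against a higher correlation as the cause. The setting also takes its p from the 2 residual degrees of freedom. Interferon genes, for one, went from an unadjusted camera p of 1.52e-08 to 0.0246. Itgav turned to a log2 fold change of -0.0095 with upper-quartile scaling and to -0.088 with the GC and length offset (0.01 to 0.08 without 1 library). Some lists that were not called changed direction in at least 1 setting, given here as adjusted p. These were the Wnt list with fry (0.971), the hypoxia list with fry (0.996) and at a mean of 5 CPM (0.861), and the matrix list with the GC and length offset (0.785). Without 1 library, adjusted p ranged from 0.484 to 0.871 for oestrogen genes, 0.345 to 0.972 for Wnt, 0.366 to 0.851 for Hedgehog, 0.00806 to 0.641 for matrix, 0.021 to 0.872 for the cell cycle, 0.531 to 0.972 for hypoxia, 0.000215 to 0.872 for ribosomal proteins, 0.00663 to 0.972 for megakaryocytes and 0.747 to 0.894 for skeletal muscle. The causes were not tested.

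Depth limits the low genes, since 1 count is worth 0.0423 to 0.0519 CPM, and the 2 libraries per group limit the rest, with 26.8% of simulated 1 log2 unit changes called.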

Other observations

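The 5 gene lists used here and the tests of a lower chondrocyte and osteoblast share, of scaling, of GC and length, of lysed red cells and of transcripts from immune cells were chosen only after the results were seen, and the other tests before. A part of the genes that make and bind hyaluronan rose beside Has1. In a list written after Has1 was noticed, 7 of the 19 tested genes other than Has1 were higher and 1 lower (median log2 fold change 0.18, with 11 of 19 above 0). Of 7 enzymes that supply the precursors of hyaluronan 4 rose, with Uap1 going from 308 to 786 mean CPM (log2 fold change 1.35 ± 0.11 SE, edgeR adjusted p = 0.00285), Gfpt2 from 730 to 1654, Ugdh from 524 to 1006 and Ugp2 from 116 to 267, while Gfpt1, Pgm3 and Gnpnat1 did not pass (log2 fold changes -0.35, -0.04 and 0.71). The binding proteins Tnfaip6 (log2 fold change 3.68 ± 0.28 SE) and Cd44 (1.95 ± 0.13 SE), the receptor of hyaluronan, rose too, while Cemip, which takes part in its breakdown, fell by 0.80 ± 0.12 SE log2 units. Has2 was at 3.21 and 1.74 mean CPM and did not pass (edgeR adjusted p = 0.503). Camera gave the list without Has1 an adjusted p of 2.71e-07 over the 5 added lists (unadjusted p = 0.0575 with an estimated correlation). Of 9 genes of EGF receptor ligands and receptors other than Ereg and Egfr, which led to the list, 3 were higher and 0 lower. Areg had 0 counts in sham and was at least 43.8-fold higher. Hbegf rose from 497 to 1243 mean CPM, and Errfi1, a feedback inhibitor of the receptor, from 1331 to 2951. The camera adjusted p was 2.39e-05 without Ereg and Egfr. With an estimated correlation the camera p was 0.0471, which was not adjusted over the 5 added lists and is not a call. Egf, Tgfa and Erbb2 did not pass, with log2 fold changes of -0.85 ± 1.01, -0.20 ± 0.25 and 0.04 ± 0.21 SE.

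Cholesterol synthesis genes had lower values beside Sqle, which led to the list, with 1 of the 21 other genes called lower (Stard4), 2 of the 21 above 0 and a median log2 fold change of -0.42. With Sqle, 2 were called lower, and 1 to 4 under the other scalings tried. Hmgcs1 went from 213 to 148 mean CPM and Cyp51 from 183 to 120, and neither passed (edgeR adjusted p = 0.0522 and 0.0501). Without Sqle the camera adjusted p was 4.14e-06. With an estimated correlation the camera p was 0.0344, which was likewise not adjusted over the 5 added lists and is not a call. Genes were also grouped by the stem of their symbol, and of 241 families with at least 8 tested members 7 were called by camera, all higher, and 0 with an estimated correlation (all adjusted p = 0.993). These were Cxcl (6 of 9 higher), Ifi (3 of 10), Klf (5 of 15), Sema (5 of 20), Ccl (2 of 8), Gbp (2 of 8) and Anxa (2 of 10), and 0 members of any of the 7 fell. The median of each family was above 0 under each scaling tried, and with the GC and length offset 3 Klf, 4 Sema and 1 Gbp genes were called. The semaphorins that rose were Sema3a, Sema3c, Sema3e, Sema3f and Sema4c, of which Sema3f had 1 count in sham.

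The first pattern weighed is the fall of cartilage and bone matrix genes beside the rise of fibroblast and stromal genes. Scaling by a few abundant genes is argued against, since a factor per library moves all genes alike, while 25 of 28 chondrocyte genes lay below the median of 16238 genes outside the lists and the 200 most abundant genes (-0.02) by more than 2 SE, with a median distance of -0.76 log2 units. So is a GC or length trend. With the offset the chondrocyte median was -0.87, while the median gene shifted by only -0.11 log2 units. In that fit 19 chondrocyte genes were called lower, a count that the shift itself favours. A lower share of chondrocytes and osteoblasts alone would raise all other cell types alike. Over members in no other list and with at least 5 CPM in sham, the mean log2 level of the skeletal muscle list changed by -0.52 ± 0.14 SE, of the erythroid list by 1.24 ± 0.17 SE and of the fibroblast list by 1.41 ± 0.28 SE, with SE between libraries. The distances from skeletal muscle were 7.9 and 6.12 SE, and 4.59 and 3.84 SE with members of at least 1 CPM in sham. Skeletal muscle (3 and 5 genes) was in all 3 pairs of lists more than 3 SE apart at both floors. Its 8 tested genes together had a median of -0.16 and a mean of 0.13 (camera adjusted p = 0.641). Each SE rests on 2 libraries per group, and the widest pairs were sought among all lists. The test therefore cannot decide, and a lower share of chondrocytes and osteoblasts stays open. A second fibroblast list, 4 of whose tested genes stand in fixed lists with results already seen, had a median log2 fold change of 1.035 (4 of 23 higher, 0 lower, camera p = 6.02e-06, 0.245 with an estimated correlation, and a median of 0.67 over the 19 other genes), and all 23 had a mean of at least 1 CPM in sham cells. Its 5 members with at least 100 CPM in sham had a median of -0.04 (Cilp went from 5030 to 3972 and Islr from 698 to 493 mean CPM), and a high level in the other cells would hide a small share of fibroblasts, so more fibroblast cells in the sort after ovariectomy cannot be told apart from a change within the cells. A change in gene expression of the stem cells after ovariectomy stays open beside it and was not tested.

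The second pattern is the rise of erythroid, granulocyte and lymphocyte genes, from a sort stained against CD45 and Ter119. RNA of lysed red cells was weighed as the main source of the erythroid genes. As counted, haemoglobin, the most abundant transcript of red cells, gained 38.0 CPM (at most 49.8 over pairs of libraries). This is 21.3% of the 179 CPM gained by the 11 other erythroid genes together (at least 124). Reads of the near-identical haemoglobin genes may be split or left uncounted, and how they were handled is not given. The comparison therefore cannot decide on lysed red cells. Haematopoietic progenitor cells in the sort remain a candidate explanation that cannot be told apart from a change within the cells. A second list of their genes had a median log2 fold change of 0.91, under the bound of 1 set beforehand, and 3 of 19 genes were higher and 0 lower (camera p = 0.00329, 0.345 with an estimated correlation). Kit went from 0.513 to 6.37 and Epor from 0.0223 to 2.76 mean CPM, whereas Myb and Gata2, also progenitor genes, went from 7.67 to 5.61 and from 4.17 to 3.01 and did not pass, and 11 of the 19 had a mean of at least 1 CPM in sham cells.

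The third pattern is the rise of inflammatory and immediate-early genes. Transcripts carried in by immune cells cannot be told apart from a change within the cells. Ptprc (CD45), an antigen stained for in the sort, had a log2 fold change of -0.57 ± 0.44 SE and did not pass. In all, 43 lymphocyte, monocyte and granulocyte genes gained 240 CPM together, 15.7% of the 1523 CPM gained by the inflammatory list and 1.77% of the 13570 CPM gained by the immediate-early list, and no library of immune cells gives the ratios to expect. A bound set beforehand on the leading cytokine genes alone was dropped for the same reason, and its outcome is not given here. A stronger dissociation response in the ovariectomy libraries cannot be told apart from a response to ovariectomy, since the 8 core immediate-early genes had a median log2 fold change of 0.38, between the bounds set beforehand, and only Fos and Fosb of them were called higher. The labels name no digestion batch, and a response of the cells to ovariectomy was not tested apart from these.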
